A study of Arabidopsis thaliana with 47 samples.

How the data were processed

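Transcript levels were measured on 47 Affymetrix ATH1 arrays of Arabidopsis Col-0 root protoplasts. Roots of seedlings aged 10 days were digested for 4 h, and the cells were transfected for 25 min and kept overnight. They carried either GR::bZIP1, a fusion of the transcription factor bZIP1 to a glucocorticoid receptor domain, or the empty vector. Dexamethasone (DEX, 10 µM) moves the fusion into the nucleus. Nitrogen (N) was 20 mM KNO3 with 20 mM NH4NO3 for 2 h, against 20 mM KCl. Cycloheximide (CHX) blocks protein synthesis. Cells positive for the red fluorescent marker of the vector were sorted and their RNA was amplified before labelling.

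The deposited values are on a log2 scale, and the submitters' processing notes name GCRMA, with no version. The scale was read from the values. The lowest value was 2.30 in both bZIP1 arms and 2.29 in the empty-vector arm, and to 3 decimals it differed among all 3 arms (2.298, 2.303 and 2.287). The arms were therefore evidently summarised in separate runs, which is read from the values and not given in the sources used here. Levels of different arms are for this reason not on 1 scale, while effects within an arm are differences on its own scale. Of the 22810 probe sets, 64 controls were left out and 22746 were tested. Arrays hold no counts, so their number and the level of a probe set above the floor limit the precision. Between 30.7% and 33.5% of an array's values lay at the floor.

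Samples were grouped by vector, CHX, N and DEX from the labels into 12 groups. Each arm (bZIP1 with CHX, bZIP1 without CHX, empty vector with CHX) is a 2 by 2 design of N and DEX. The bZIP1 arm with CHX has 6 arrays per group, from 2 preparations (Bioreps) of 3 treatment replicates each. The bZIP1 arm without CHX has 3 per group, and the empty-vector arm has 3 per group except 2 for DEX without N. Treatment replicates of 1 preparation may not be separate cultures, so errors describe the spread between arrays.

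Each effect was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05 on the adjusted p. The DEX effect is the mean of the DEX groups minus that of the groups without DEX, averaged over N, and the N effect is built likewise. The interaction is the DEX effect with N minus that without N. Biorep was a covariate in the bZIP1 arm with CHX and in fits of all 47 arrays. After removal of group means, all 108 pairs of arrays of the same Biorep correlated above 0.1, with a median of 0.541. Replicate numbers did not meet that rule elsewhere: 18 of 36 treatment replicate pairs, 14 of 18 pairs without CHX and 8 of 15 empty-vector pairs passed it, so these were not blocked. Differences between arms in the DEX or N effect, and the level differences between arms, came from 1 fit of all 47 arrays. The labels name preparations in the bZIP1 arm with CHX alone. In these differences, vector or CHX therefore cannot be told apart from preparation. Overlaps of calls were tested over all 22746 probe sets with Fisher's exact test, one-sided for enrichment, adjusted over the table of overlaps. Probe sets that stay at the floor in an arm cannot be called there, so the expected overlaps are too low. In all, 15 limma results were computed.

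Gene names came from a table that matched 13436 of the 22746 probe sets to 1 locus of the TAIR10.1 annotation, which was used for names alone. The other 9310 probe sets were tested but are not named. Named genes follow a rule: the 10 largest rises and 10 largest falls past the threshold for the DEX and N effects in the bZIP1 arms, and 5 and 5 for other results, matched to 1 gene. Within an arm they also had to move the same way in every matched pair of groups. Up to 4 members per gene list with the lowest adjusted p could be named too. Other genes named are members of the tested lists, and the values of a gene in results other than the one that selected it are given for comparison. The level of bZIP1 itself is not analysed here, because no probe set could be matched to it.

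There were 20 gene lists fixed before the arrays could be seen, with 267 members, of which 44 were named on the array. A further 24 lists were written after the name table was seen and before the data were examined, and 1 list was written after results were seen. Lists with at least 3 named members, 29 in all, were tested in 13 contrasts with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation. The adjustment was within the earlier or the later lists of a contrast.

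Analyses were tested on simulated data, with 200 changed probe sets and 3 simulations. Each probe set had 1 spread, taken from the fit of all 47 arrays, and arrays varied independently. Changes were placed only in probe sets with a mean over 4. The rates therefore do not cover low levels, a spread that differs between arms or treatment replicates that vary together. For the DEX effect in bZIP1 cells with CHX, 73.1% of changes of 0.5 and 98.5% of changes of 1 on the log2 scale were found, and 4.57% of calls were false. Without CHX the first 2 values were 22.4% and 82.6%, in the empty vector 13.4% and 62.7%. For the interaction, changes of 1 were found in 73.6% with CHX, 14.9% without CHX and 12.4% in the empty vector, where 12.1% of calls were false. In a first simulation of camera with 100 unchanged lists, 11 had p under 0.05 with the preset and 10 with the estimated correlation. The number of lists was then raised to 500, which gave 26 and 21, and an alternative with a filter on low values was added for the lists.

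Before the arrays were seen, 186 other settings were chosen, 1 for each pairing of a result and a choice: a filter on low values (a group mean of at least 4), quantile normalization, a change of at least 1, only probe sets matched to 1 gene, no moderation, a fit of all arrays, a covariate left out or added, means of treatment replicates, each Biorep alone, and leaving out replicates or single arrays. For each of the 15 limma results, 100 splits of the arrays into groups of the same sizes were drawn. The splits for results between arms used the arrays of the arms compared, without the Biorep covariate. For differences in the DEX or N effect their values were first centred within each arm and Biorep. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.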

Results

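Root cells that carried GR::bZIP1 or the empty vector were profiled on 47 arrays, in 12 groups defined by vector, CHX, N and DEX. The bZIP1 cells with CHX made up 24 arrays, with 6 per group. Those without CHX made up 12 arrays, with 3 per group. The empty-vector cells, all with CHX, made up 11 arrays, with 3 per group except 2 for DEX without N. Array medians lay between 2.9 and 3.2 on the log2 scale, against a floor near 2.3. Arrays of the same group correlated with Pearson's r of 0.933 to 0.988 across probe sets in bZIP1 cells with CHX, 0.983 to 0.991 without CHX and 0.979 to 0.992 in the empty vector. In bZIP1 cells with CHX the first principal component held 45.0% of the variance, and Biorep accounted for 97.6% of it, while DEX accounted for 94.2% of the second. Locus identifiers give the chromosome in the digit after AT.

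To ask which transcripts respond when bZIP1 enters the nucleus while protein synthesis is blocked, DEX was compared with no DEX in bZIP1 cells with CHX (12 arrays against 12). AT5G08350, which encodes a GRAM domain protein, rose by 4.54 ± 0.13 (log2, SE), from a mean of 6.16 ± 0.55 to 10.7 ± 0.76 (SD, n = 12 each). The asparaginase gene ASPGB1 (AT3G16150) rose by 2.97 ± 0.20, AT1G54740 by 2.60 ± 0.14 and AT2G41190, of the amino acid transporter family, by 2.08 ± 0.20. The lipase gene DGL (AT1G05800) fell by 2.01 ± 0.15 and the pectin methylesterase gene ATPMEPCRB (AT4G02330) fell by 1.48 ± 0.16. Each of these genes moved the same way in 6 of 6 matched pairs of groups. The naming rule required this of every gene named for a large effect within an arm, so pair counts here and below are no separate support. In the empty vector the DEX effect was 0.23 ± 0.21 for AT5G08350, -0.09 ± 0.15 for ASPGB1 and -0.25 ± 0.08 for AT1G54740.

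Other genes with large rises included AT1G69570, a Dof factor, at 2.08 ± 0.13, AT1G66890 at 2.06 ± 0.20 and AT4G32950, a protein phosphatase 2C, at 2.02 ± 0.12. AT2G24130, a leucine-rich repeat kinase, rose by 1.89 ± 0.10, IAA34 by 1.89 ± 0.14 and AT1G67480, a kelch F-box gene, by 1.88 ± 0.08. Among the falls, AT4G39320 changed by -1.18 ± 0.19, AT5G54720 by -1.12 ± 0.14 and the ERF gene AT1G44830 by -1.12 ± 0.22. AT2G37810, AT1G51915, AT1G52560 (a small heat shock protein gene), AT1G55790 and AT2G23270 changed by -1.08 to -0.98. The lowest adjusted p among the 20 genes was 6.79e-15 for AT5G08350 and the highest 0.0446 for AT1G52560. By limma, 1401 of 22746 probe sets passed, 725 higher and 676 lower, of which 137 and 15 changed at least 2-fold. Of the 1401, 712 carry a gene name here. A probe set without one, singled out after its value was seen, rose by 6.26 ± 0.22 from a mean of 2.38 with 5 of 12 arrays at the floor, so that its change is a lower bound.

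Genes of amino acid breakdown rose together with DEX in these cells. Of the 6 measured genes of amino acid catabolism 5 rose and 0 fell, 5 and 0 adjusted over the list alone, and camera gave an adjusted p of 9.5e-12. On the longer list of branched-chain and lysine catabolism 8 of 11 rose, 8 adjusted over the list alone (adjusted p = 5.24e-14). This list also holds a proline dehydrogenase gene and shares members with the amino acid catabolism list. Here and below, results of these lists are therefore no separate support. The proline dehydrogenase gene AT5G38710 rose by 1.83 ± 0.11, ALDH6B2 (AT2G14170) by 0.70 ± 0.06, AT4G33150, for lysine breakdown, by 0.63 ± 0.09 and MCCA (AT1G03090), a methylcrotonyl-CoA carboxylase subunit, by 0.56 ± 0.04. Of 12 genes of the longer energy starvation list 5 rose, 7 adjusted over the list alone (adjusted p = 7.11e-07), among them AT1G18460 by 0.65 ± 0.09 and AT3G15630 by 0.64 ± 0.08. The shorter sugar starvation list had 2 measured members, too few for a test, and 1 rose, 2 adjusted over the list alone: AT3G15450, by 0.32 ± 0.07.

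Auxin genes and the longer nitrate list also held members that rose with DEX. Of 3 early auxin response genes 2 rose, 2 up and 1 down adjusted over the list alone (adjusted p = 0.00871, up). Their median was 0.30 and their mean -0.04, since IAA29 (AT4G32280) lay at -0.97 ± 0.31 with an adjusted p of 0.0785. Of 12 GH3 and Aux/IAA genes 4 rose, 4 up and 2 down adjusted over the list alone (adjusted p = 0.0243), including GH3.17 (AT1G28130) by 0.69 ± 0.08. Of 16 genes of the longer nitrate list 5 rose, 6 adjusted over the list alone (adjusted p = 7.11e-07), including GAT1_2.1 (AT1G15040) by 1.01 ± 0.07. None of the 5 genes of the shorter nitrate list passed, 0 adjusted over the list alone (adjusted p = 0.572). Of 18 expansins 3 rose and 1 fell, 3 and 1 adjusted over the list alone (adjusted p = 0.0434), and their call was lost (adjusted p = 0.11 with an estimated correlation). EXLA3 (AT3G45960) rose by 0.99 ± 0.07, and EXPA4 (AT2G39700) fell by 0.34 ± 0.10. The calls of the other lists held with an estimated correlation, with adjusted p of 0.000159 for amino acid catabolism, 0.000615 for branched-chain and lysine catabolism, 0.00585 for energy starvation, 0.000337 for the longer nitrate list, 0.0205 for early auxin response and 0.0415 for GH3 and Aux/IAA. Both measured bZIP genes of groups C and S1 fell, 2 adjusted over the list alone: bZIP44 (AT1G75390) by 0.59 ± 0.17 and BZIP53 (AT3G62420) by 0.18 ± 0.04. Among 5 early stress genes CML37 (AT5G42380) fell by 0.22 ± 0.02, with 1 up and 1 down adjusted over the list alone (adjusted p = 0.572). The count of 1401 fell to 726 without the Biorep covariate and to 174 when the treatment replicates of a Biorep were averaged. It was 706 in Biorep 1 alone, 384 in Biorep 2 alone, and 771 to 885 without 1 of the treatment replicates.

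**Figure D1:**
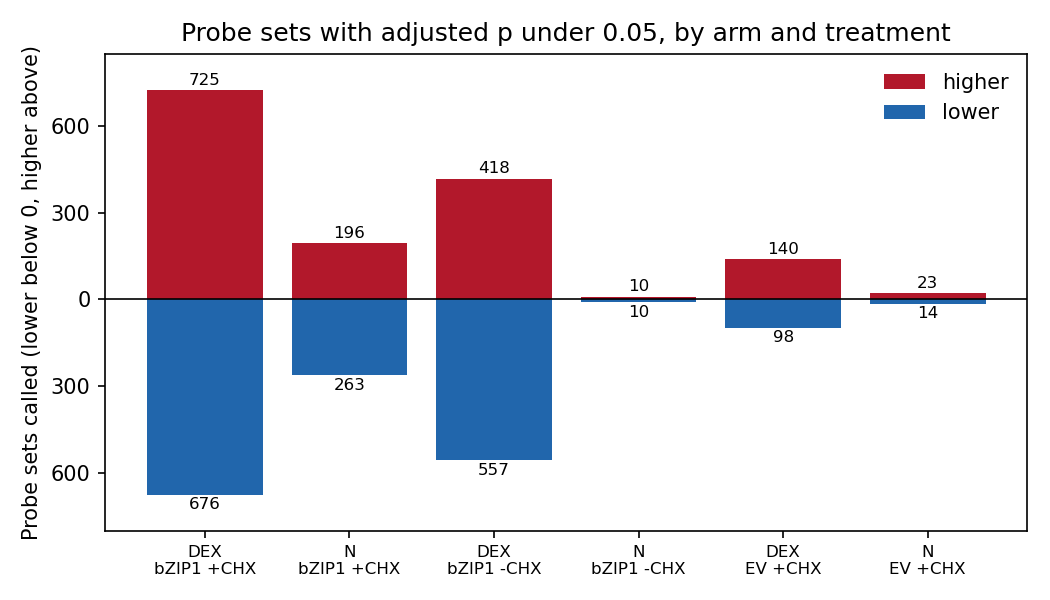
Probe sets with an adjusted p under 0.05 (y axis, number of probe sets; higher above 0 in red, lower below 0 in blue) for the DEX and N effects in each arm (x axis). DEX gave 725 higher and 676 lower in bZIP1 cells with CHX, and N gave 10 and 10 in bZIP1 cells without CHX.

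DEX was compared with no DEX in bZIP1 cells without CHX as well (6 arrays against 6), where proteins made in response to bZIP1 can act. AT5G08350 rose by 3.188 ± 0.110 and AT2G41190 by 2.72 ± 0.12, as both had with CHX. GH3.3 (AT2G23170), an auxin-conjugating enzyme gene, rose by 2.64 ± 0.20, AT2G47500 by 2.54 ± 0.19 and EXLA3 by 2.18 ± 0.15. The receptor-like cytoplasmic kinase gene AT5G65530 fell by 2.17 ± 0.29, AT4G02090 fell by 1.99 ± 0.17 and AT1G28400 fell by 1.84 ± 0.29. In the empty vector, with CHX, the DEX effect was -0.13 ± 0.04 for GH3.3, 0.47 ± 0.48 for AT2G47500 and -0.20 ± 0.07 for AT5G65530.

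Further rises without CHX were of AT5G66650 (2.3 ± 0.13), AT5G01610 (2.1 ± 0.14), AT2G34670 (1.99 ± 0.09), the UDP-glycosyltransferase gene AT3G46700 (1.98 ± 0.15) and AT1G62480 (1.91 ± 0.07). Further falls were of AT1G08670 (-1.80 ± 0.15), the dirigent gene AT4G13580 (-1.80 ± 0.22), the peroxidase gene AT5G66390 (-1.59 ± 0.16), AT5G40590 (-1.57 ± 0.17), the acyltransferase gene AT5G42830 (-1.52 ± 0.20), AT4G17280 (-1.48 ± 0.13) and AT3G22620 (-1.46 ± 0.08). Each of the 20 moved the same way in 3 of 3 matched pairs, with adjusted p of 1.05e-05 to 0.00941. By limma 975 probe sets passed, 418 higher and 557 lower, of which 82 and 88 changed at least 2-fold. Of the amino acid catabolism list 2 of 6 rose, 2 adjusted over the list alone (adjusted p = 0.0776). Of branched-chain and lysine catabolism 3 of 11 rose, 3 adjusted over the list alone (adjusted p = 0.039, and 0.52 with an estimated correlation). The count of 975 fell to 199 to 313 without 1 of the replicates, which leaves 2 arrays per group. It rose to 1582 with the filter on low values, which leaves fewer probe sets to adjust over.

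The DEX responses with and without CHX shared many genes, and others differed. Of the probe sets that passed in both arms, 231 rose in both, against 13.3 expected if independent (Fisher's exact test, adjusted p = 7.32e-241), and 90 fell in both, against 16.6 (adjusted p = 1.59e-39). Opposite calls were few, 8 that rose with CHX and fell without it and 7 the other way. Of the 1401 calls with CHX 76.4% had the same sign without it. Across 9596 expressed probe sets, which are not independent replicates, Spearman's rho of the effects was 0.291 and Pearson's r was 0.446. The direct test of the difference called 1014 probe sets, 648 with a higher and 366 with a lower effect with CHX, of which 145 and 35 differed at least 2-fold. AT5G65530 differed by 2.79 ± 0.29, with a rise of 0.62 ± 0.18 with CHX against its fall without it. AT4G02090 differed by 2.06 ± 0.16, AT1G22885 by 1.95 ± 0.26, AT3G54120 by 1.82 ± 0.16 and AT1G08670 by 1.81 ± 0.13. On the other side, GH3.3 differed by -2.34 ± 0.13, having risen by 0.30 ± 0.03 with CHX, AT2G47500 by -2.31 ± 0.39, DGL by -2.0 ± 0.20, the defensin-like gene LCR69 (AT2G02100) by -1.99 ± 0.46 and AT2G34670 by -1.98 ± 0.16. Without CHX, DGL had group means of 2.30 to 2.31, at the floor, where a fall cannot be seen. With CHX, AT1G08670 (2.35 to 2.60), AT2G34670 (2.53 to 2.71) and LCR69 (2.5 to 3.04) lay near the floor, which leaves AT1G08670 little room for a fall. GH3.3 instead lay high with CHX. Its mean was 5.75 without CHX or DEX, and 9.97 when these arrays were pooled with those with both. It was 8.38 with DEX alone, and 10.65 when pooled with CHX alone. Both levels with CHX thus lay above these pooled means. Whether that limited a further rise was not tested. The adjusted p of the 10 named genes lay between 6.78e-15 and 0.00511.

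Among the lists, UDP-glycosyltransferases had a higher DEX effect with CHX than without it in 7 of 47 genes and a lower one in 0, 8 and 1 adjusted over the list alone (adjusted p = 0.00103, and 0.00519 with an estimated correlation). UGT73C7 (AT3G53160) differed by 1.3 ± 0.26 and UGT88A1 (AT3G16520) by 1.08 ± 0.19; both fell without CHX, by 1.13 ± 0.18 and by 0.97 ± 0.15. Amino acid catabolism had a higher effect with CHX in 1 of 6 genes, 3 adjusted over the list alone (adjusted p = 0.000466, and 0.0158 with an estimated correlation), and MCCA differed by 0.53 ± 0.09. Early auxin response had a lower effect in 1 of 3 genes, GH3.3, 1 adjusted over the list alone (adjusted p = 0.000466, and 0.0136 with an estimated correlation). The high level of GH3.3 with CHX bears on this list too. Branched-chain and lysine catabolism had 1 of 11 higher, 2 adjusted over the list alone (adjusted p = 0.00103, and 0.224 with an estimated correlation). Energy starvation had 1 of 12 higher, 1 adjusted over the list alone (adjusted p = 0.0277, and 0.413 with an estimated correlation). The 1014 became 537 without the Biorep covariate and 509 to 629 without 1 of the replicates. It became 647 when the treatment replicates of each Biorep were averaged. That fit kept the arrays without a Biorep single, among them all those without CHX.

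**Figure D2:**
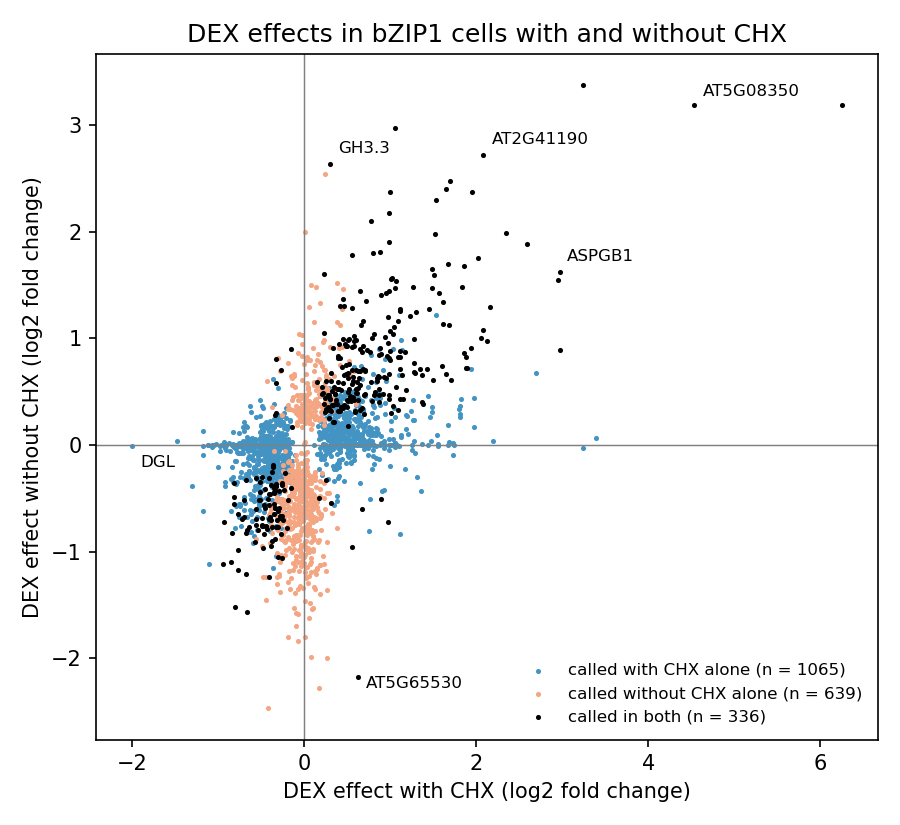
DEX effect of each probe set called in at least 1 of the arms, with CHX (x axis, log2 fold change) against without CHX (y axis, log2 fold change), in bZIP1 cells. Of the 336 probe sets called in both (black) 231 rose in both and 90 fell in both, 1065 were called with CHX alone (blue) and 639 without CHX alone (orange).

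DEX was also compared with no DEX in empty-vector cells, which lack the fusion protein (5 arrays with DEX against 6). AT2G47950 rose by 3.42 ± 0.14, AT2G47960 by 3.04 ± 0.09, the calmodulin-like genes AT1G76640 by 2.86 ± 0.17 and AT1G21550 by 2.22 ± 0.21, and AT3G22060 by 2.68 ± 0.14. AT1G72240 fell by 1.69 ± 0.28, the late embryogenesis abundant genes AT3G15670 and AT3G02480 fell by 1.42 ± 0.16 and by 1.22 ± 0.18, the ERF gene AT1G33760 fell by 1.1 ± 0.18 and AT5G17460 fell by 0.98 ± 0.16. In bZIP1 cells with CHX the DEX effect of AT2G47950 was 0.19 ± 0.29 and that of AT1G76640 was -0.37 ± 0.20, and neither passed. By limma 238 probe sets passed, 140 higher and 98 lower, with 46 and 14 at least 2-fold. The 10 named genes had adjusted p of 3.26e-05 to 0.0408 and moved the same way in 3 of 3 matched pairs. Of 6 WRKY genes WRKY22 (AT4G01250) rose by 0.70 ± 0.08, 2 adjusted over the list alone (adjusted p = 0.0147, and 0.235 with an estimated correlation). Of 12 energy starvation genes AT3G10020 fell by 0.20 ± 0.03, 2 adjusted over the list alone (adjusted p = 0.0363, and 0.235 with an estimated correlation). Without replicate 2 the count of 238 became 8. Without replicate 1 or 3, or without its DEX array without N alone, it became far higher. Each of those fits leaves 1 array of DEX without N, assumed to vary like the other groups.

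The direct test of bZIP1 cells against the empty vector, both with CHX, called 1031 probe sets with a different DEX effect, 562 higher and 469 lower in bZIP1 cells, of which 196 and 114 differed at least 2-fold. The effect was higher for AT5G08350 by 4.31 ± 0.22, ASPGB1 by 3.06 ± 0.32, AT1G54740 by 2.85 ± 0.22, PYRB (AT3G20330), the aspartate transcarbamoylase gene, by 2.57 ± 0.15 and AT5G45630 by 2.32 ± 0.16. PYRB rose by 1.67 ± 0.10 in bZIP1 cells and fell by 0.90 ± 0.13 in the empty vector. The effect was lower for AT1G76640 (-3.23 ± 0.29), AT2G47950 (-3.22 ± 0.41), AT1G21550 (-2.73 ± 0.29), AT2G47960 (-2.65 ± 0.29) and the peroxidase gene AT5G06730 (-2.27 ± 0.30). Adjusted p lay between 4.43e-16 and 1.4e-06. Of the 7 lists called for DEX in bZIP1 cells, 6 were higher than in the empty vector. Early auxin response was not called, with 0 of 3 genes, 2 up and 1 down adjusted over the list alone (adjusted p = 0.175, and 0.283 with an estimated correlation). Amino acid catabolism had 3 of 6 higher, 5 adjusted over the list alone (adjusted p = 9.61e-11), branched-chain and lysine catabolism 4 of 11, 6 over the list alone (3.04e-11), energy starvation 5 of 12, 6 over the list alone (1.13e-05) and the longer nitrate list 5 of 16, 6 over the list alone (1.05e-10). Expansins had 3 higher and 1 lower of 18, 3 and 1 over the list alone (0.0125), and GH3 and Aux/IAA 2 higher of 12, 4 over the list alone (0.0125). With an estimated correlation the 6 adjusted p were 4.38e-05, 0.001, 0.0168, 4.2e-07, 0.0387 and 0.0191. Of the 1401 DEX calls in bZIP1 cells with CHX, 50.2% had the same sign in the empty vector, and rho across the 9596 expressed probe sets was 0.0318. The count of 1031 fell to 584 without the Biorep covariate and to 555 without replicate 2.

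Nitrogen was compared with KCl in bZIP1 cells with CHX (12 arrays against 12) to find its response when protein synthesis is blocked. The small heat shock gene AT1G54050 rose by 1.67 ± 0.21, AT5G10210 by 1.49 ± 0.20 and AT1G49500 by 1.21 ± 0.11. The FKBP-type chaperone gene AT5G48570 rose by 0.97 ± 0.18, the co-chaperone gene Hop3 (AT4G12400) by 0.93 ± 0.19 and the late embryogenesis abundant gene AT2G42560 by 0.90 ± 0.13. AT2G18180 fell by 1.38 ± 0.17, the peroxidase gene AT1G68850 fell by 1.18 ± 0.17 and AT3G50050 fell by 1.11 ± 0.24. NRPD7 (AT3G22900), an RNA polymerase subunit gene, fell by 0.88 ± 0.12, BGLU31 (AT5G24540), a beta-glucosidase gene, fell by 0.86 ± 0.14 and DPE1 (AT5G64860), a starch breakdown gene, fell by 0.86 ± 0.12. BGLU31 had 2 of 12 arrays with N at the floor, so its fall is a lower bound.

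Also higher with N were AT2G41190 (0.86 ± 0.20), the 6-phosphogluconate dehydrogenase genes AT5G41670 (0.83 ± 0.14) and AT1G64190 (0.79 ± 0.14), and AT5G20885 (0.77 ± 0.10). Also lower were AT1G50590 (-0.97 ± 0.17), AT5G40590 (-0.92 ± 0.19), AT4G19865 (-0.92 ± 0.16) and AT5G02590 (-0.90 ± 0.21). Each of the 20 genes moved the same way in 6 of 6 matched pairs, with adjusted p of 6.86e-06 to 0.0283. By limma 459 probe sets passed, 196 higher and 263 lower, of which 12 and 7 changed at least 2-fold. Of the 5 measured genes of the nitrate response 4 rose, 4 adjusted over the list alone (adjusted p = 4.39e-10, and 1.24e-05 with an estimated correlation): AT5G41670, AT1G64190, AT1G68670 by 0.57 ± 0.07 and AT1G25550 by 0.20 ± 0.03, the last 2 encoding HHO factors, while AT3G25790 had an effect of 0.03 ± 0.05. Of the longer list 7 of 16 rose, 8 adjusted over the list alone (adjusted p = 2.19e-13, and 2.25e-06 with an estimated correlation). Amino acid catabolism had 3 of 6 higher, 4 adjusted over the list alone (adjusted p = 6.86e-05, and 0.0112 with an estimated correlation), with MCCB (AT4G34030) at 0.45 ± 0.10 and IVD (AT3G45300) at 0.45 ± 0.09. Branched-chain and lysine catabolism had 3 of 11 higher, 4 adjusted over the list alone (adjusted p = 0.00221, and 0.29 with an estimated correlation). The heat shock list had 1 measured member, AT1G53540, which rose by 0.68 ± 0.14. The count of 459 fell to 95 without the Biorep covariate and to 6 with averaged treatment replicates. It was 29 in Biorep 1 alone, 24 in Biorep 2 alone and 69 to 138 without 1 of the treatment replicates, and it rose to 690 with the filter on low values and to 813 in the fit of all 47 arrays.

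Without CHX the N response of bZIP1 cells (6 arrays against 6) held 20 probe sets by limma, 10 higher and 10 lower, and 1442 at an unadjusted p under 0.05. With CHX, each Biorep alone, also 6 arrays against 6, gave 29 and 24. The 6 named genes were the peroxidase gene AT5G64120 (-0.81 ± 0.10, adjusted p = 0.0368), AT1G65570 (-0.57 ± 0.07), EXPA4 (-0.46 ± 0.06), the calreticulin gene CRT1b (AT1G09210; -0.44 ± 0.05), AT5G58200 (-0.135 ± 0.016) and AT2G20595 (0.028 ± 0.003), each in 3 of 3 matched pairs. AT2G20595 was not above background, with means of 2.33 and 2.30. Of 79 cytosolic ribosome genes 0 passed, 0 adjusted over the list alone, while their median was -0.13 (adjusted p = 9.82e-11, and 0.875 with an estimated correlation). The count of 20 was 99 with the filter on low values, 162 in the fit of all 47 arrays, 5 to 7 without 1 of the replicates and 59 without replicate 2 of N with DEX. When probe sets matched to 1 gene were tested alone, 0 passed.

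In the empty vector N against KCl (6 arrays against 5) raised AT1G49500 by 2.13 ± 0.23, AT1G54050 by 2.03 ± 0.14, AT5G20885 by 1.07 ± 0.13, AT5G39590 by 0.74 ± 0.06 and AT4G32950 by 0.58 ± 0.07. AT4G02210 fell by 0.73 ± 0.08, AT3G50370 fell by 0.48 ± 0.06, AT1G23300 fell by 0.16 ± 0.02 and ETP2 (AT3G18910) fell by 0.120 ± 0.004, the last 2 near the floor. By limma 37 probe sets passed, 23 higher and 14 lower. Of the nitrate response 1 of 5 rose, AT1G25550 by 0.275 ± 0.035, and 4 adjusted over the list alone (adjusted p = 1.56e-06, and 0.00785 with an estimated correlation). Of the longer nitrate list 3 of 16 rose, 9 adjusted over the list alone (adjusted p = 5.33e-08, and 0.00868 with an estimated correlation). Amino acid catabolism had 0 of 6 called and 3 higher adjusted over the list alone (adjusted p = 0.000346, and 0.0146 with an estimated correlation). The lists of ATG8 genes (adjusted p = 0.0179, and 0.303 with an estimated correlation), energy starvation (0.0096, and 0.248) and branched-chain and lysine catabolism (0.0096, and 0.248) were higher, with 0 genes called and 0, 1 and 1 adjusted over the list alone. The 69 plastid genome probe sets had a median of -0.06, with 0 called and 0 adjusted over the list alone (0.00475, and 0.642). Without replicate 2 the count of 37 became 6. Without replicate 1 or 3, or without its DEX array without N alone, it became far higher. Each of those fits leaves 1 array of DEX without N, assumed to vary like the other groups. The count was 139 with the filter (63 higher, 76 lower), 275 in the fit of all 47 arrays (107 and 168) and 69 with replicate as a covariate (32 and 37), with more lower than higher in each.

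The N effects of bZIP1 cells with CHX and of the empty vector pointed the same way for 95.4% of the 459 calls, with rho of 0.899 over those calls and 0.512 over the expressed probe sets. Both arms called 13 of the same probe sets higher, against 0.198 expected (Fisher's exact test, adjusted p = 4.08e-21). The direct test called 17 with a different N effect, 14 higher and 3 lower in bZIP1 cells, among them AGL61 (AT2G24840) by 1.53 ± 0.29, AT2G03750 by 0.90 ± 0.18, AT2G38350 by 0.62 ± 0.12, AT3G49400 by 0.42 ± 0.09 and AT5G42840 by 0.36 ± 0.08, and with lower effects AT1G70900 by -0.65 ± 0.13 and AT3G63220 by -0.34 ± 0.07. AGL61 lay near the floor in bZIP1 cells, with group means of 2.30 to 2.69, and AT2G38350 and AT5G42840 had means of 2.42 to 2.68 over both vectors. The count was 4 with the filter on low values and 11 after quantile normalization. Without replicate 1 or 3 it became far higher, in fits that leave 1 empty-vector array of DEX without N.

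Between bZIP1 cells with and without CHX, 78 probe sets differed in their N effect by limma, 48 higher and 30 lower with CHX. AT5G10210 differed by 1.46 ± 0.29, AT1G54050 by 1.35 ± 0.29, AT4G13580 by 1.13 ± 0.26, the lipase gene DLAH (AT1G30370) by 0.99 ± 0.14 and AT4G02090 by 0.92 ± 0.16. Lower effects with CHX were those of AT2G18180 (-1.36 ± 0.28), AT3G02480 (-0.97 ± 0.23), NRPD7 (-0.88 ± 0.18), AT3G49130 (-0.87 ± 0.18) and AT1G22890 (-0.81 ± 0.17). Of the nitrate response 0 of 5 were called and 2 adjusted over the list alone (adjusted p = 0.000766, and 0.0024 with an estimated correlation). Of the longer nitrate list 1 of 16, AT5G10210, was higher with CHX and 7 adjusted over the list alone (adjusted p = 6.98e-07, and 2.4e-05 with an estimated correlation). Of 79 cytosolic ribosome genes 1 was higher, 1 adjusted over the list alone (adjusted p = 7.69e-05, and 0.671 with an estimated correlation). Of the 459 N calls with CHX 79.1% had the same sign without it. The count of 78 became 39 without the Biorep covariate. It became 43 with the treatment replicates of each Biorep averaged and the arrays without CHX kept single.

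**Figure D3:**
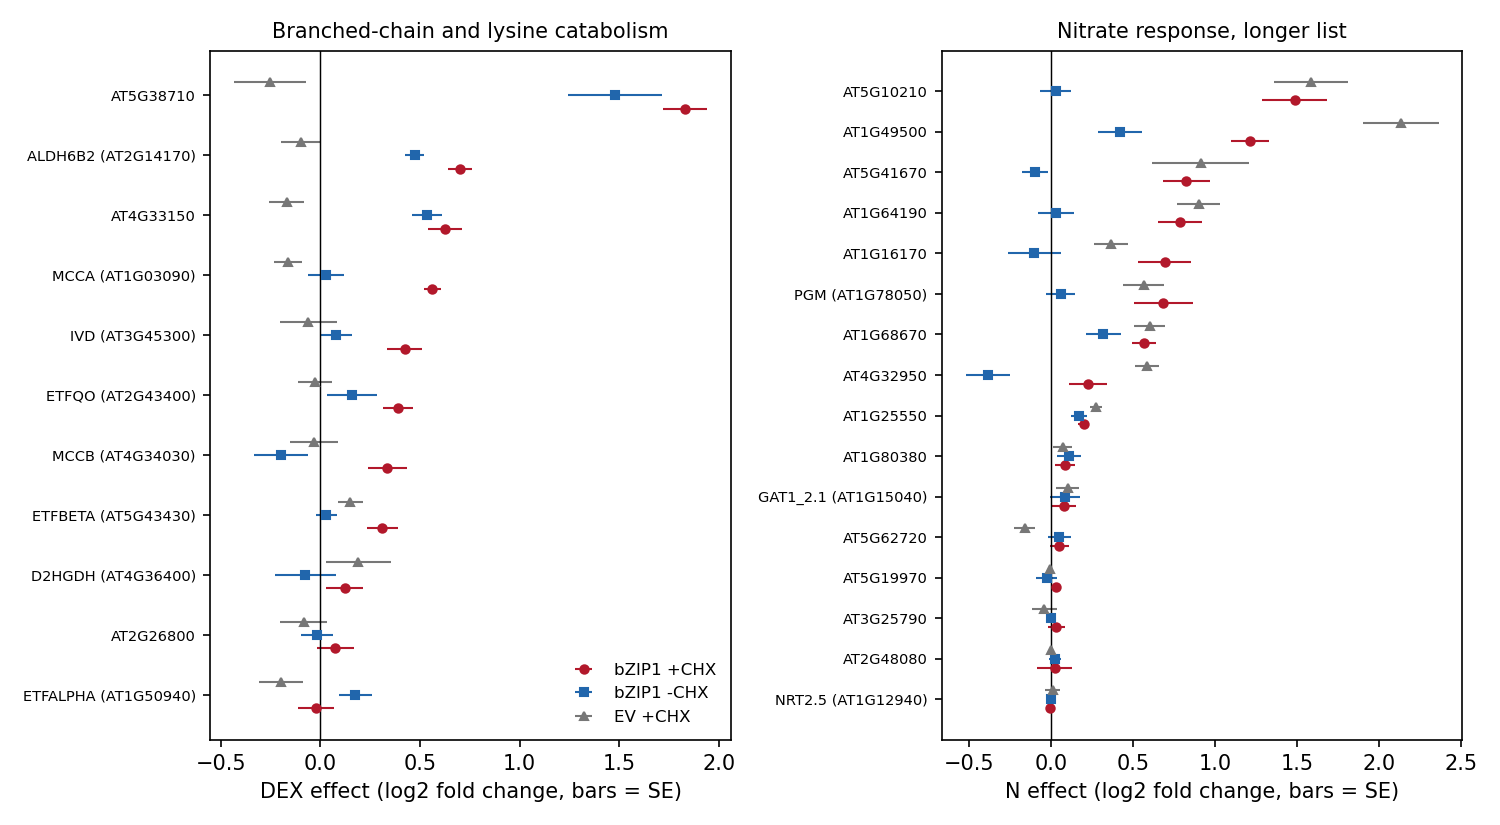
DEX effect of the genes of branched-chain and lysine catabolism (left) and N effect of the genes of the longer nitrate list (right), as log2 fold change with SE (x axes), in bZIP1 cells with CHX (red circles), bZIP1 cells without CHX (blue squares) and empty-vector cells (grey triangles). With DEX 8 of the 11 genes rose in bZIP1 cells with CHX, and with N 7 of the 16.

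Whether the response to DEX differs with nitrogen was asked with the interaction. In bZIP1 cells with CHX 0 probe sets passed by limma, with 554 at an unadjusted p under 0.05, and without CHX 0 passed, with 611. The count without CHX was 4 to 8 without 1 of the replicates and 0 to 11 without a single array. Simulated interactions of 1 on the log2 scale were found in 73.6% with CHX and 14.9% without it, in probe sets with a mean over 4. With CHX the nitrate response (median -0.13) and amino acid catabolism (median -0.14) had an adjusted p of 0.0412 each, with 0 genes called and 0 adjusted over the list alone, and 0.122 and 0.179 with an estimated correlation. Without CHX the ATG8 genes (median 0.19) had 0.0206 and the plastid genome (median 0.23) 1.45e-12, with 0 called and 0 adjusted over the list alone, and 0.431 and 0.323 with an estimated correlation. In the empty vector 8 passed, 4 higher and 4 lower, with 732 at an unadjusted p under 0.05. AT1G23300 (-0.31 ± 0.03), ETP2 (-0.228 ± 0.008) and AT5G60610 (-0.036 ± 0.002) were the named ones, and all lay near the floor, with group means of 2.3 to 2.76. Cytosolic ribosome genes had an adjusted p of 0.0293 there, with 0 of 79 called and 1 adjusted over the list alone, and 0.659 with an estimated correlation. The count of 8 became 0 with the filter on low values and 2 without replicate 2. Without replicate 1 or 3 it became far higher, in fits that leave 1 array of DEX without N.

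Genes that responded to N in bZIP1 cells with CHX often responded to DEX there as well. Of the 459 N calls 188 were DEX calls: 91 fell with both (7.82 expected if independent), 45 rose with both (6.25 expected), 47 fell with N and rose with DEX (8.38 expected) and 5 rose with N and fell with DEX (5.83 expected). Fisher's exact test gave adjusted p of 7.69e-71, 3.83e-25, 2.15e-21 and 0.928. AT1G49500 rose by 1.27 ± 0.11 with DEX and AT5G10210 by 0.81 ± 0.20, and AT5G40590 fell with DEX by 0.67 ± 0.19, each moving as it had with N. The 188 became 41 without the Biorep covariate and 3 when a change of at least 2-fold was asked for.

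Levels between arms were compared last, on values that were not made on 1 scale, so that their sizes hold any offset between the arms. Between bZIP1 cells with and without CHX 17568 probe sets differed by limma, 5567 higher and 12001 lower, and 4597 of them by less than 0.1 on the log2 scale. With a difference of at least 2-fold 2567 were higher and 3286 lower, with the filter on low values 4563 and 5976, and after quantile normalization 5603 and 7881. AT5G19240 was higher by 9.65 ± 0.05, AT5G52750 by 9.10 ± 0.07, AT1G14550 by 8.96 ± 0.10, AT5G52760 by 8.94 ± 0.05 and MSRB9, a methionine sulfoxide reductase gene, by 8.80 ± 0.07. AT2G32430 (-4.65 ± 0.05), AT5G16450 (-4.62 ± 0.08), AT5G58520 (-4.06 ± 0.07), AT5G08750 (-3.94 ± 0.06) and AT1G62480 (-3.94 ± 0.09) were lower. Several of these levels lay near the floor: means without CHX were 2.45 for AT5G19240, 2.83 for AT5G52750, 2.63 for AT1G14550 and 2.36 for AT5G52760, and means with CHX were 2.72 for AT2G32430, 2.53 for AT5G58520 and 2.62 for AT5G08750. Between bZIP1 and empty-vector cells with CHX and without DEX 13621 differed, 8203 higher and 5418 lower in bZIP1 cells, and 4693 of them by less than 0.1. AT5G15910 was higher by 2.71 ± 0.13, AT5G25360 by 2.65 ± 0.11, AT5G26260 by 2.45 ± 0.21, AT3G52860 by 2.33 ± 0.06 and AT2G28680 by 2.30 ± 0.19, where AT5G15910 and AT5G25360 had means of 2.37 and 2.67 in the empty vector, near the floor. BGLU31 (-4.16 ± 0.18), AT3G57460 (-3.83 ± 0.18), AT5G38310 (-2.94 ± 0.18), AT5G58210 (-2.85 ± 0.06) and BGLU32 (-2.85 ± 0.15) were lower. Between vectors, the direction with more probe sets depended on the setting: 441 were higher and 810 lower at 2-fold, 3074 and 4470 with the filter, and 4194 and 4245 of 8439 after quantile normalization over all arrays.

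The other lists held few measured genes or gave no list call in these 13 contrasts. Lists with 1 or 2 measured members, not tested as groups, were cytokinin response, circadian clock, ABA and dehydration, root hair and epidermis, cortex and endodermis, shoot photosynthesis, reference genes and the shorter ribosome list, and with DEX in bZIP1 cells with CHX 0 of their members passed, 0 adjusted over the list alone. The lists of nitrogen assimilation, hypoxia, stele and root cap or meristem had 0 named members on the array.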

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

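The tests of a DEX response shared by both vectors and of separate scaling of the arms, and the count of 211 probe sets above the floor, were chosen only after the result was seen; for the spread of 2 empty-vector arrays, counts without single arrays had been seen.

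The splits argue against chance for the DEX counts of the 3 arms, since 1 of 100 splits, the real one, gave as many calls in each. The counts were 1401 against at most 1 in the other splits for bZIP1 with CHX, 975 against 3 without CHX and 238 against 17 in the empty vector. The splits move single arrays as if each were separate, which treatment replicates may not be, and 1 in 100 is the lowest share they can give. The same holds, with the same limits, for the N counts, with 459 against 3, 20 against 2 and 37 against 11. For the interaction in the empty vector chance cannot be excluded, since 9 of 100 splits gave at least its 8 calls (highest other 21). For the interactions in bZIP1 cells the splits decide nothing, since 100 of 100 must give at least the 0 calls found (highest other 3 with CHX and 2 without).

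With the same limits, the splits argue against chance for the DEX difference between the vectors (985 in the fit used for the splits, highest other 15). They do so too for both differences with CHX, in DEX (924, highest other 3) and in N (66, highest other 3). For the N difference between the vectors they do not: 54 of 100 splits gave at least the 2 calls of that fit, with a highest other of 12. None of these splits can tell vector or CHX apart from a difference between the preparations of the arms. For levels the counts were 17340 with against without CHX (highest other 8146) and 13599 between vectors (highest other 5). These splits decide nothing, since arms summarised in separate runs can differ by an offset whatever the treatment.

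In the empty vector 238 probe sets were called for DEX. A DEX response that cells with either vector share is argued against as the cause of all of them, since 51.7% of the 238 (123) had the same sign in bZIP1 cells with CHX. Noise of the 2 DEX arrays without N is argued against for probe sets that respond to DEX with N. Of 376 probe sets with an unadjusted p under 0.01 in the arrays with N, 87.5% had the same sign in those without N, though 8 alone passed the adjusted threshold with N. The test starts from the arrays with N, so it cannot speak to calls that rest on the 2 arrays. ETP2 and AT5G60610, both near the floor, had DEX effects of 0.117 and 0.018 and interactions of -0.228 and -0.036, so their DEX effect lay mostly without N. Calls in both arms exceeded those expected in either direction: 12 rose in both (4.46 expected) and 21 fell in both (2.91). Another 17 fell in the empty vector and rose in bZIP1 cells (3.12), and 15 did the reverse (4.16). These expected numbers are too low, since probe sets that stay at the floor cannot be called. What stays open is a response that some of these genes share, or a response of these cells to DEX, for which no test was run. Noise also stays open for calls that rest on the 2 DEX arrays without N.

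The DEX effect differed with CHX for 1014 probe sets. After quantile normalization over all arrays 1178 differed. An offset between the arms cancels in this difference, and this normalization cannot undo a separate summary of the probes. Separate scaling of the arms is thus argued against only as far as quantile normalization can correct it. Of 264 probe sets that fell without CHX and had a higher effect with it, 31.4% (83) had a mean under 4 with CHX, against 20.8% of all that fell without CHX, and for these a fall hidden near the floor cannot be told apart. It can apply to a part of the 264 at most, since their median level with CHX was 5.97 and 211 lay above the floor by at least the size of their fall. A need for newly made protein, which CHX prevents, stays open and was not tested, and so does the reverse case of genes at the floor without CHX, such as DGL. A high level with CHX that limits a further rise, as may hold for GH3.3, stays open as well.

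N calls and DEX calls overlapped in 188 probe sets in bZIP1 cells with CHX. With permuted DEX labels the overlap of the N calls with as many top-ranked probe sets was at most 127 (median 32). These fits estimate the variance anew, and a real DEX effect adds to it, so this overlap can be too low. A variance estimate shared by both tests therefore stays open as a cause. The use of the same arrays in both tests is argued against for probe sets that fell with both. N in Biorep 1 and DEX in Biorep 2 shared 53 falls where 5.78 were expected, a ratio of 9.17. The reverse pairing gave 6.51. Falls with N that rose with DEX numbered 19 against 6.85 (2.77) and 50 against 9.04 (5.53). The expected numbers include probe sets that stay at the floor and cannot be called, so all these ratios are too high. By how much was not tested, so the ratio of 2.77 cannot show an excess. A biological link between N and bZIP1 stays a hypothesis, found and tested on the same arrays.

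Of 164 pairs of a measure and a group 4 held an array far from the others, where chance gives about 1 in 20, or 8.2. Only groups with at least 4 arrays were tested, which are those of bZIP1 cells with CHX (6 arrays each). The other arms were not screened. The 4 were AT2G24130 at 8.59 in replicate 1 of Biorep 2 without N or DEX (others 7.76 to 8), AT5G10210 at 6.62 in replicate 1 of Biorep 1 with N alone (5.61 to 5.99), and, in replicate 3 of Biorep 2 with N and DEX, AT1G49500 at 7.67 (7.86 to 7.94) and AT4G19865 at 6.72 (5.82 to 6.02).

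Effects that passed a direct test of the difference between groups were as follows. The DEX effect differed between the vectors for 1031 probe sets, with AT5G08350 at 4.31, ASPGB1 at 3.06, AT1G54740 at 2.85, PYRB at 2.57, AT5G45630 at 2.32, AT1G76640 at -3.23, AT2G47950 at -3.22, AT1G21550 at -2.73, AT2G47960 at -2.65 and AT5G06730 at -2.27. The N effect passed this test between the vectors for 17, where the splits do not exclude chance and the filter on low values left 4, with AGL61 at 1.53, AT2G03750 at 0.90, AT2G38350 at 0.62, AT3G49400 at 0.42, AT5G42840 at 0.36, AT1G70900 at -0.65 and AT3G63220 at -0.34. The DEX effect differed with CHX for AT5G65530 at 2.79, AT4G02090 at 2.06, AT1G22885 at 1.95, AT3G54120 at 1.82, AT1G08670 at 1.81, GH3.3 at -2.34, AT2G47500 at -2.31, DGL at -2.0, LCR69 at -1.99 and AT2G34670 at -1.98. The N effect differed with CHX for 78, with AT5G10210 at 1.46, AT1G54050 at 1.35, AT4G13580 at 1.13, DLAH at 0.99, AT4G02090 at 0.92, AT2G18180 at -1.36, AT3G02480 at -0.97, NRPD7 at -0.88, AT3G49130 at -0.87 and AT1G22890 at -0.81. The interaction passed for 8 in the empty vector, where the splits do not exclude chance, the filter on low values left 0 and the named genes lie near the floor, with AT1G23300 at -0.31, ETP2 at -0.23 and AT5G60610 at -0.04.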

How the results depend on the processing

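The filter on low values for the gene lists was the only alternative chosen after seeing the data, and gave 21 list calls within the arms where 27 were found. For the named genes 2562 values were recomputed: 2014 kept direction and call, 548 kept direction and lost the call, and 0 reversed. These genes were picked as the largest changes on the same arrays, and several settings leave the change itself unaltered. A reversal was therefore unlikely from the start. Counts that moved over 1.5 times are given here; unless a reason is named, the cause was not tested.

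Asking for a 2-fold change left, for DEX, N and (empty vector) interaction, 152 and 19 in bZIP1 cells with CHX, 170 and 2 without CHX, and 60, 9 and 0 in the empty vector. It left 310 (DEX) and 1 (N) that differed between vectors, 180 and 12 that differed with CHX, and 5853 and 1251 for levels with CHX and between vectors. Testing only probe sets matched to 1 gene, which are fewer, gave 680 and 198 with CHX, 449 and 0 without CHX, 87, 9 and 2 in the empty vector, 451 and 11 between vectors, 470 and 31 with against without CHX, and 10218 and 8129 for levels.

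The filter on low values, which leaves fewer probe sets, gave 690 for N with CHX, 1582 and 99 for DEX and N without CHX, 411, 139 and 0 in the empty vector, 4 for the N difference between vectors, and 10539 and 7544 for levels. Quantile normalization gave 1 interaction without CHX, 2 in the empty vector, 11 for the N difference between vectors and 8439 for levels between vectors. Without moderation there were 11 for N without CHX and 5 for the empty-vector interaction. An unadjusted p under 0.01 gave 69, 128 and 183 interactions in the 3 arms and an overlap of 523 for DEX with and without CHX.

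Without the Biorep covariate counts were 726 for DEX and 95 for N with CHX, 584 for the DEX difference between vectors, 537 and 39 for the DEX and N differences with CHX, and 41 for the overlap of N and DEX, which was 3 at 2-fold. Means of treatment replicates, which are fewer samples, gave 174, 6, 647 and 43 for DEX, N and their differences with CHX. For the differences, arrays without a Biorep stayed single, so these counts do not rest on averaged replicates in both arms. Biorep 1 alone gave 706 for DEX, 29 for N, 1 interaction and 6 for the N difference between vectors, and Biorep 2 alone 384, 24 and, for the DEX difference between vectors, 686. The fit of all 47 arrays gave 813 for N with CHX, 162 for N and 25 interactions without CHX, and 482, 275 and 5 in the empty vector. Replicate as a covariate gave 69 for N and 1 interaction in the empty vector. An estimated correlation left 12 of the 27 list calls within the arms, and 11 of the 14 in the differences between arms, where no other list alternative was run. With only probe sets matched to 1 gene the 27 became 33.

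Without 1 replicate, DEX, N and interaction counts were 771 to 885, 69 to 138 and 0 to 0 in bZIP1 cells with CHX, 199 to 313, 5 to 7 and 4 to 8 without CHX, and 8 to 784, 6 to 689 and 2 to 584 in the empty vector. Between vectors they were 555 to 934 (DEX) and 10 to 177 (N), with against without CHX 509 to 629 and 57 to 79, and for levels 17106 to 17390 and 12144 to 12841. Without single arrays, counts without CHX were 738 to 1019 for DEX, 9 to 59 for N (59 without replicate 2 of N with DEX) and 0 to 11 for the interaction. In the empty vector they were 148 to 831, 28 to 695 and 5 to 544. Leaving out replicate 1 or 3 of DEX without N gave DEX counts of 813 and 831, N counts of 695 and 653 and interactions of 536 and 544, the lone array left being assumed to vary like the other groups. Leaving out replicate 2 of N with DEX gave 154 and replicate 2 of N alone 148 for DEX; for the interaction, replicate 1 of N with DEX gave 16, replicate 1 without N or DEX 20 and replicate 2 of N alone 5.

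The alternative on the level of bZIP1 was not run, since no probe set was matched to it. Between 30.7% and 33.5% of an array's values lay at the floor, where a fall cannot be seen.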

Other observations

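The list of other heat shock genes was written after chaperone genes were seen among the largest rises with N in bZIP1 cells with CHX.

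A hypothesis is that N may raise heat shock genes in cells with either vector when CHX is present. In the empty vector 11 other heat shock genes, none of them named among the largest rises, had a camera p of 0.00328 and 0.0813 with an estimated correlation, with 9 of 11 above 0, a median of 0.165 and 0 called. In bZIP1 cells with CHX the p was 0.00124 and 0.0831 with an estimated correlation, with 1 called and a median of 0.203, and without CHX it was 0.495 with a median of 0.033. The rise in the empty vector fits the hypothesis with the preset correlation and is lost with the estimated one. Whether it differs between arms was not tested.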
